A study of Homo sapiens with 2 samples.

How the data were processed

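RNA of THP-1 cells was sequenced at 2 glucose concentrations, with 1 library for each. THP-1 is a line of human monocytic leukaemia cells that is used as a model of monocytes. Per the labels' protocols, the cells were grown in RPMI 1640 medium, RNA was isolated with TRIzol, and polyadenylated RNA was depleted of ribosomal RNA with RiboMinus kits. The labels give 5 mM glucose for the normal-glucose sample and 25 mM for the high-glucose sample. The treatment field of both samples reads 25 mM for 72 hours, and the normal-glucose sample is described as untreated, so the 72 hours were taken to apply to the high-glucose sample.

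The submitters' processing notes name Bowtie, Partek and the human genome build hg18, without versions. Read length, use of strand, and the treatment of reads with several matches are not given in the sources used here. The table holds 33244 entries for 31716 RefSeq transcript accessions and 21299 gene symbols. Per the file headers, it gives raw reads per transcript for each library. The values are estimated counts as deposited by the authors: they are fractional where a gene has several transcripts and add up to whole numbers per gene, within 0.01 reads, for 99.95% of genes in both libraries. The deposited table also gives RPKM (reads normalised to transcript length and library total). Per the file headers, both RPKM columns belong to high glucose. In the first of them, however, 13267 entries with more than 50 normal-glucose reads all gave a library total between 12879256 and 12879459 when set against the normal-glucose reads and the transcript length. Set against the high-glucose reads they gave totals from 384000 to 841000000. That RPKM column was therefore given to no sample, and RPKM values were recomputed from the reads where they were needed. The RPKM columns imply library totals of 12879352 and 16616568 reads, of which 66.7% and 64.8% were assigned to genes.

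The estimated counts of all entries of a symbol were summed and rounded to whole numbers. Of the symbols, 55 entries had been turned into dates, as spreadsheet software does, and 53 of them were renamed from their RefSeq accession. A transcript was listed at several places, including the 588 entries on alternate haplotypes, for 658 genes, and 233 genes shared the exact position of another symbol. The libraries were scaled with TMM factors of 0.965 for normal and 1.04 for high glucose (edgeR 4.0.16 in R 4.3.3). Assigned reads came to 8595765 in the normal-glucose library and 10771071 in the high-glucose library, and 1 read was worth 0.120 and 0.0896 scaled CPM. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

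With 1 library per glucose concentration there is no replicate test, and no p-value is given. Each gene has the fold of its scaled reads with an exact 95% Clopper-Pearson counting interval, computed from the share of its reads in each library. A gene with at least 20 reads over both libraries was called higher or lower when the bound of this interval nearer to 1 was at least 1.5-fold. The intervals cover counting error only, and each comparison is between these 2 libraries.

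Gene lists, 41 in number, were fixed together with the size rule before the data were examined. For lists with at least 5 measured members, the median log2 fold was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins and drawn with replacement. A list was called apart when its percentile was below 2.5 or above 97.5. For log2 values 0.5 reads were added per library. The same description was used for the genes of each chromosome. Isoform shares were compared for genes with at least 2 transcripts and 100 reads in each library, and a transcript was counted when its share differed by at least 25 percentage points. The coordinates are those of the deposited table, on hg18, and for a gene listed at several places they are those of the place with most reads.

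The genes named in the text follow a rule fixed at the same time: the 12 genes called higher and the 12 called lower with the largest near bound, up to 4 called members of each list (or the 2 with the highest expression where none was called), 12 genes chosen in advance and the 6 genes with the largest isoform difference. Some genes that the rule takes are not reported here. Genes outside the rule that stand behind a small count were named after their values were seen. Genes with near-identical copies (ORM1 and ORM2, TMSB15A and TMSB15B, HLA, metallothionein and ribosomal protein genes) are uncertain, because reads may have been divided between the copies. So are genes that overlap another gene: of the genes called, 320 overlap a gene on the opposite strand and 73 have a transcript at several places or at a shared position.

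Transcript GC content was taken from the sequences of GENCODE release 29 for 12958 of the tested genes (97.1%), by RefSeq accession for 11732 and by symbol for 1226. No coordinates of that annotation were used. A lowess trend (span 0.3) of log2 fold on GC content and then on transcript length was taken out as an alternative, and calls were made again. Counts, folds and percentiles made that way are given as corrected. This alternative was chosen after the data were seen, as were 2 others: scaling to the library totals implied by RPKM, and leaving out genes at several or shared places. The other alternatives were total, upper-quartile and median-of-ratios scaling, no read minimum or one of 100, a 99.9% interval, a fold limit of 2, the most abundant transcript of each gene, RPKM with a pseudocount of 1, unmatched random lists, and stricter limits for isoforms.

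The calling rule was tested on simulated data drawn for the genes of these 2 libraries. With counting noise only, 0 of 13137 unchanged genes were called, the 95% intervals covered the true fold in 95.5% of genes, and 72 of 99 genes changed by 2-fold and 97 of 98 changed by 4-fold were recovered. When spread between cultures with a coefficient of variation of 0.2 was added, 732 of 13128 unchanged genes were called and the intervals covered the true fold in 46.9% of genes. In the simulation with counting noise only, where genes vary independently, 8 of 200 random lists of 30 unchanged genes stood apart. That number does not apply to lists whose genes move together. Levels of XIST and of genes on the Y chromosome were left out.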

Results

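Transcript levels were measured in THP-1 cells, a human monocytic leukaemia line, kept in normal glucose (5 mM) or in high glucose (25 mM, given as 72 hours). The comparison addresses which genes are expressed differently at the higher glucose concentration. There was 1 library per concentration, with 8595765 reads assigned to genes in normal glucose and 10771071 in high glucose, and 13349 genes had at least 20 reads over both. None of the differences has a replicate check. The intervals given in parentheses are 95% counting intervals, so a difference between cultures that has nothing to do with glucose is not covered by them.

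In the high-glucose library, interferon-stimulated genes and genes of the ATF4 amino acid response were higher almost as whole groups. TXNIP and ARRDC4, the best known targets of the glucose-sensing transcription factors MondoA and ChREBP, were higher too. The list of such targets as a whole was not apart from random lists. Genes of mitosis, DNA replication, cholesterol synthesis, cytosolic ribosomes and MHC class II were lower, and so were housekeeping genes, taken as a background list. In all, 1356 genes were higher and 1263 were lower by at least 1.5-fold at the near bound of the interval, and 10730 were neither. By at least 5-fold at the near bound, 72 genes were higher and 8 were lower. Of the genes called, 51.8% were higher; scaled to the total of gene counts, which moves the median of all genes by 0.10 on the log2 scale, 1707 were higher and 938 lower, or 64.5% higher.

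**Figure D1:**
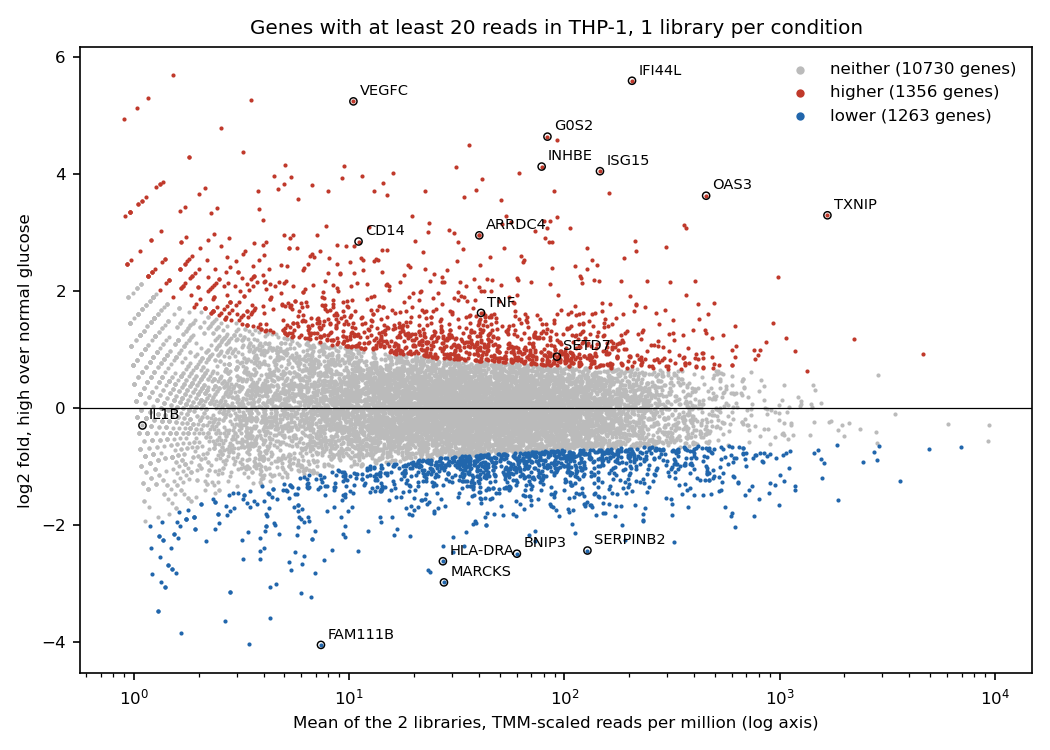
Each point is 1 of the 13349 genes with at least 20 reads, plotted by its mean scaled CPM in the 2 libraries (log axis) and its log2 fold of high over normal glucose. Red points are the 1356 genes called higher and blue points the 1263 called lower; IFI44L lies at the top with a fold of 48.6.

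The fold depended on base composition. Transcripts with more G and C were relatively higher in the high-glucose library: the median log2 fold was -0.28 in the fifth of the genes with the lowest GC content and 0.42 in the fifth with the highest, and across 12958 genes, which are not independent replicates, Spearman's rho was 0.39 for GC content and 0.14 for transcript length. With this trend taken out, 898 genes were higher and 960 lower, and 756 and 704 of these had the same call without the correction. No gene had opposite calls.

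**Figure D2:**
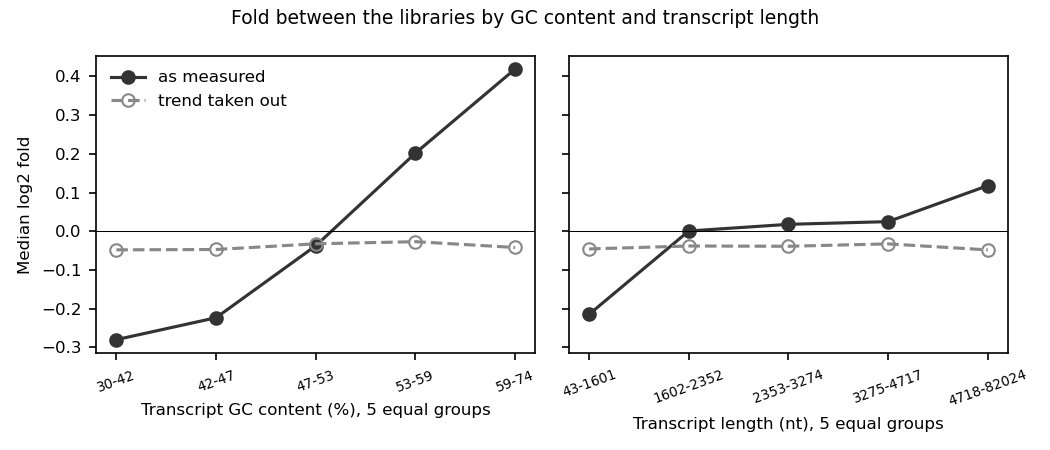
Median log2 fold of high over normal glucose in 5 groups of genes of about equal number, ordered by transcript GC content (left, %) or length (right, nucleotides). Filled points are as measured and rise from -0.28 to 0.42 with GC content; open points have the trend taken out.

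IFI44L had the largest near bound of all genes called. It had 69 reads in normal and 4504 in high glucose, a 48.6-fold difference (38.3 to 62.5), and lies on chromosome 1 from 78858676 to 78884418 (hg18). Its neighbour IFI44, at 78888065 to 78902351, was 24.2-fold higher (18.8 to 31.8). Among the 12 highest genes, 5 belong to the list of interferon-stimulated genes: IFI44L, IFI44, IFI27 (22.9-fold, 15.4 to 35.6), ISG15 (16.6-fold, 14.0 to 19.8) and OAS3 (12.4-fold, 11.4 to 13.5). G0S2, an inhibitor of triglyceride lipase, was 25.1-fold higher (19.1 to 33.7). The growth factor gene VEGFC went from 4 to 228 reads, 42.4-fold (16.3 to 157). INHBE, a subunit of activin, was 17.6-fold higher (13.8 to 22.7), the stress-response gene NUPR1 15.3-fold (11.2 to 21.4), the potassium channel subunit gene KCNE1 17.6-fold (12.1 to 26.7), and SIGLEC1, a macrophage lectin that interferon also induces, 12.9-fold (11.1 to 14.9; corrected 8.09-fold). ORM1, an acute-phase protein gene with the near-identical copy ORM2, was 16.3-fold higher (12.5 to 21.5).

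At the other end, FAM111B fell from 116 to 9 reads, 17.3-fold (8.82 to 38.8), and MPZL1 from 54 to 4 reads, 18.1-fold (6.69 to 69.0). MARCKS, a substrate of protein kinase C, was 7.91-fold lower (6.12 to 10.4), the adhesion molecule gene CEACAM6 6.99-fold (5.35 to 9.24), and HSD11B1, which makes active glucocorticoid from cortisone, 6.82-fold (5.23 to 9.02). SERPINB2, an inhibitor of plasminogen activators, went from 1791 to 446 reads and was 5.40-fold lower (4.86 to 6.0). BNIP3, a hypoxia target in mitochondria, was 5.61-fold lower (4.81 to 6.57) and HLA-DRA 6.15-fold (4.85 to 7.87). The remaining 4 of the 12 lowest were TMSB15B (12.7-fold, 5.82 to 32.7, corrected 7.11-fold, with the near-identical copy TMSB15A), PNCK, UGT3A2 and FAM70A, the last 3 with at most 100 reads in either library.

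Of 15 measured MondoA and ChREBP targets, 6 were higher (corrected 5) and 1 was lower (corrected 2). TXNIP, which restrains glucose uptake, went from 2559 to 33740 reads, 9.81-fold higher (9.42 to 10.2), at chromosome 1 from 144149819 to 144153985. ARRDC4 was 7.78-fold higher (6.14 to 9.98), MLXIPL, which encodes ChREBP itself, 7.35-fold (5.30 to 10.4) and TBC1D16 5.87-fold (3.95 to 9.04). The list as a whole was not apart, with a median log2 fold of 0.23 (corrected 0.02) at percentile 87.1 of the random lists (corrected 68.5). Of 24 glycolysis and lactate genes, 2 were higher (corrected 1), 8 lower and 14 neither: LDHA was 3.45-fold lower (3.31 to 3.60), ALDOC 5.10-fold lower (4.18 to 6.26) and GPI 2.72-fold lower (2.52 to 2.93), while the lactate exporter SLC16A3 was 2.43-fold higher (2.17 to 2.72). The median of this list was at percentile 2.67, short of the limit, and at 0.04 with the GC and length trend taken out. In the polyol, hexosamine and O-GlcNAc list, 2 of 12 were higher and 3 lower, with the aldose reductase gene AKR1B1 3.08-fold lower (2.63 to 3.62), the glyoxalase gene GLO1 4.09-fold lower (3.91 to 4.27), UAP1 1.80-fold lower (1.58 to 2.05; corrected 1.57-fold, no longer called) and OGT 1.99-fold higher (1.93 to 2.06); the list was at percentile 20.8. Of 10 pentose phosphate genes, 1 was higher (TKTL1, 2.40-fold, 2.24 to 2.57) and 0 lower (corrected 2), and the list was at percentile 8.46.

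**Figure D3:**
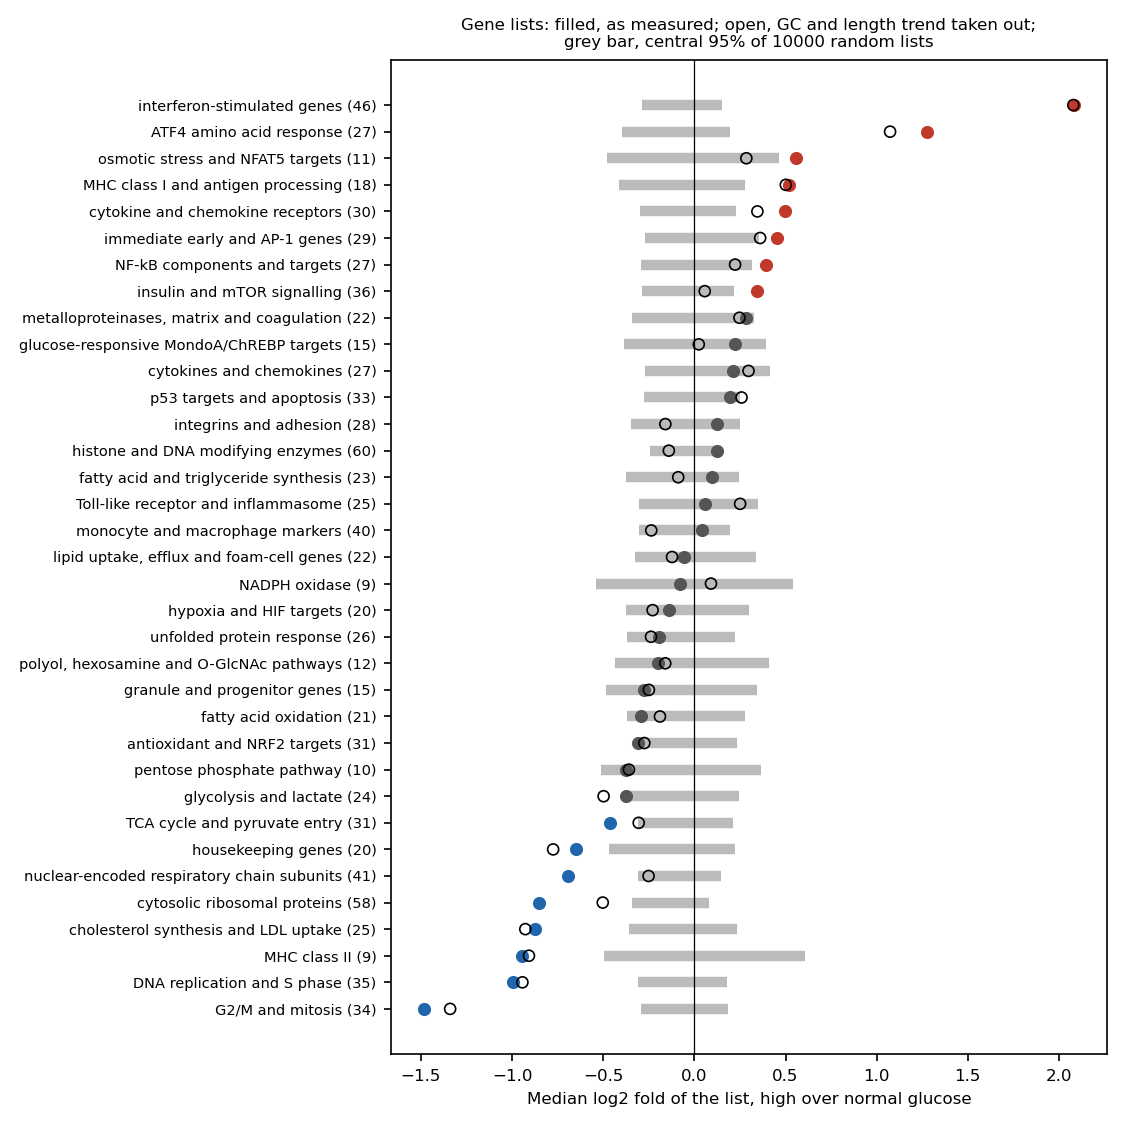
Median log2 fold of high over normal glucose for 35 gene lists, with the number of measured members in parentheses; grey bars span the central 95% of 10000 random lists. Red and blue points are lists apart on the higher or lower side, dark grey points are not apart, and open points have the GC and length trend taken out; interferon-stimulated genes lie at 2.08 and mitosis genes at -1.49.

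Of the 35 lists with enough measured members, 8 were apart on the higher side and 8 on the lower side, where random lists would give 1.75. That number takes genes as moving independently, whereas the genes of a list may move together and some lists share genes. Interferon-stimulated genes stood furthest out: 41 of 46 were higher and 0 lower, the median was 4.24-fold, and their reads together went from 18785 to 92666. Interferon genes themselves were almost silent, with 1 read in normal and 4 reads in high glucose over 21 type I, II and III genes. In the list of MHC class I and antigen processing, whose genes interferon also induces, 8 of 18 were higher and 0 lower, with HLA-F 2.69-fold (2.14 to 3.42), HLA-E 2.15-fold (1.97 to 2.35) and the peptide transporter gene TAP1 2.16-fold (2.0 to 2.34). Reads of the HLA genes cannot be assigned to one copy with certainty, and without genes at several or shared places this list was at percentile 96.2 and no longer apart.

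The ATF4 amino acid response, which cells mount when amino acids run short or the integrated stress response is active, was higher in 22 of 27 genes and lower in 0, with a median of 2.42-fold. The hormone gene STC2 was 13.1-fold higher (10.8 to 16.1), the mTOR inhibitor gene DDIT4 8.41-fold (7.76 to 9.13), CHAC1, which degrades glutathione, 7.56-fold (6.41 to 8.96) and SESN2 5.21-fold (4.65 to 5.86). The unfolded protein response was not apart: 3 of 26 genes were higher (corrected 5) and 8 lower, at percentile 21.3, with the sensor gene ERN1 4.53-fold higher (3.51 to 5.90) but the chaperone genes CALR 3.60-fold (3.46 to 3.74) and HSP90B1 2.72-fold lower (2.63 to 2.81) and MANF 2.39-fold lower (2.04 to 2.81). Among p53 and apoptosis genes 9 of 33 were higher (corrected 5) and 2 lower, at percentile 94.5 (corrected 99.7), with the cell-cycle inhibitor gene CDKN1A 5.80-fold higher (5.17 to 6.53) and ZMAT3 6.03-fold (3.01 to 13.7). Osmotic stress and NFAT5 targets were apart on the higher side at percentile 99.04, with 3 of 11 higher, 3 lower (corrected 1) and the water channel gene AQP1 9.84-fold higher (6.79 to 14.8); with the trend taken out the list was at percentile 95.02 and no longer apart. An osmotic control for the normal-glucose culture is not given in the sources used here, so higher glucose and higher osmolarity are not separated in any difference reported. In the osmotic stress list, the osmolyte and amino acid transporter genes SLC5A3 and SLC38A2 were 1.96-fold (1.71 to 2.24) and 1.88-fold (1.82 to 1.95) higher. SLC38A2 is also a member of the ATF4 list. AKR1B1, given above with the polyol genes, belongs to the osmotic stress list as well and was 3.08-fold lower (2.63 to 3.62). Of the insulin and mTOR signalling genes, 6 of 36 were higher (corrected 4) and 0 lower, among them SOCS1 (5.30-fold, 2.52 to 12.9), SOCS3 (3.46-fold, 2.12 to 5.92), FOXO1 (2.57-fold, 1.91 to 3.52) and EIF4EBP1 (2.15-fold, 2.0 to 2.32); the list was at percentile 99.87, and at 93.2, no longer apart, with the trend taken out.

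**Figure D4:**
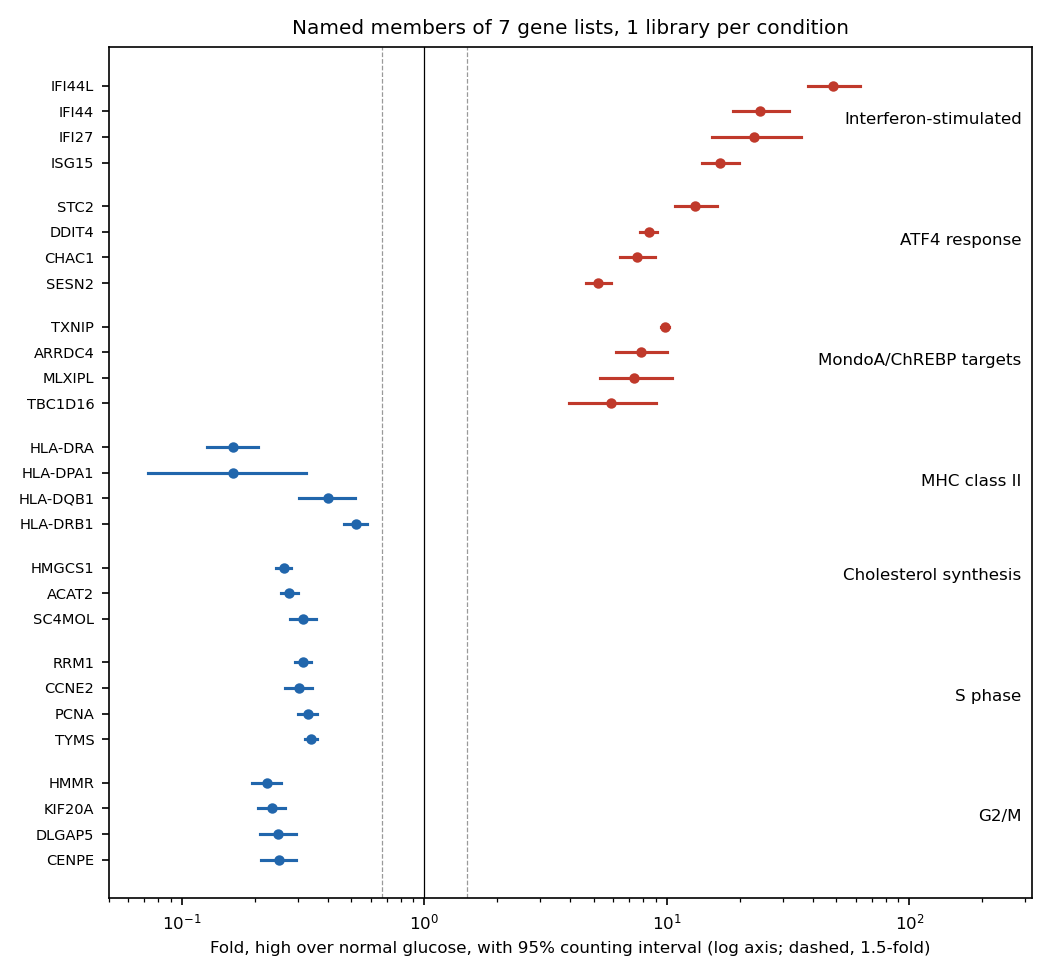
Fold of high over normal glucose (log axis) for named members of 7 gene lists. Points are folds, lines are 95% counting intervals and dashed lines mark 1.5-fold in either direction; red members were called higher and blue members lower.

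Proliferation genes were lower. Of 34 G2/M and mitosis genes, 33 were lower and 0 higher, with a median 2.80-fold lower. HMMR was 4.47-fold lower (3.91 to 5.13), the kinesin gene KIF20A 4.27-fold (3.76 to 4.87), DLGAP5 4.01-fold (3.40 to 4.75) and the centromere motor gene CENPE 3.98-fold (3.38 to 4.71). Of 35 DNA replication and S phase genes, 22 were lower and 0 higher: RRM1, a subunit of ribonucleotide reductase, was 3.18-fold lower (2.95 to 3.43), CCNE2 3.30-fold (2.91 to 3.76), PCNA 3.03-fold (2.77 to 3.32) and TYMS 2.93-fold (2.77 to 3.10). Both lists lay below all 10000 random lists, with and without the GC and length trend. KIF20A, CCNE2 and TYMS overlap a gene on the opposite strand.

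Cholesterol synthesis and LDL uptake genes were lower in 13 of 25 and higher in 1 (corrected 0), with a median log2 fold of -0.88 that lay below all random lists. HMGCS1 was 3.81-fold lower (3.55 to 4.09), ACAT2 3.60-fold (3.32 to 3.91) and SC4MOL 3.16-fold (2.79 to 3.57). ACAT2 overlaps TCP1 on the opposite strand. Fatty acid and triglyceride synthesis was not apart, at percentile 85.2, with 3 of 23 higher (corrected 1) and 1 lower (corrected 3): FASN was 1.75-fold lower (1.67 to 1.84; corrected 3.24-fold) and ACSL1 2.65-fold higher (2.42 to 2.90). Fatty acid oxidation, at percentile 7.19, had 1 of 21 higher (PPARD, 2.36-fold, 2.18 to 2.57) and 1 lower (PECI, 2.17-fold, 1.67 to 2.84; corrected 0). Of the lipid uptake, efflux and foam-cell genes, 3 of 22 were higher (corrected 1) and 5 lower (corrected 3), at percentile 35.6. There the sterol carrier gene NPC2 was 3.52-fold lower (3.23 to 3.85) and FABP5 3.82-fold lower (3.21 to 4.56), APOE was 2.77-fold higher (1.86 to 4.23; corrected 2.01-fold, no longer called), and the scavenger receptor gene CD36 had a fold of 1.13 (0.916 to 1.40).

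Cytosolic ribosomal protein genes were lower in 43 of 58 (corrected 19) and higher in 0, for example RPL11 by 2.79-fold (2.69 to 2.90), RPL23 by 2.76-fold (2.62 to 2.91; corrected 1.65-fold), RPS25 by 2.65-fold (2.55 to 2.75) and RPL5 by 2.63-fold (2.55 to 2.70). These short transcripts have many processed pseudogenes, so their reads are uncertain. Nuclear-encoded subunits of the respiratory chain were lower in 20 of 41 (corrected 6) and higher in 0, with NDUFB8 2.82-fold (2.5 to 3.18) and COX6B1 2.40-fold lower (2.19 to 2.64); the median log2 fold was -0.69, and -0.25, no longer apart, with the GC and length trend taken out. TCA cycle and pyruvate entry genes were lower in 6 of 31 (corrected 4) and higher in 0 (corrected 1), at percentile 0.06 (corrected 1.27), with FH 2.31-fold (2.11 to 2.52), SUCLG2 1.88-fold (1.60 to 2.21), SDHB 1.79-fold (1.65 to 1.94) and MDH2 1.70-fold lower (1.60 to 1.80). With the trend taken out, SUCLG2, SDHB and MDH2 were no longer called. Housekeeping genes, taken as a background list, were also apart on the lower side, with 10 of 20 lower (corrected 14) and 0 higher (corrected 1). Their median log2 fold was -0.65 (corrected -0.77). Those lower included TFRC (3.77-fold, 3.52 to 4.05), TUBB (3.14-fold, 3.04 to 3.24) and TUBA1B (2.97-fold, 2.91 to 3.04). The TCA cycle median, -0.47 (corrected -0.31), was not below that of this background list. The ribosomal protein and respiratory chain medians, -0.85 and -0.69, were below it as measured, but not with the trend taken out (-0.50 and -0.25). Antioxidant and NRF2 targets were lower in 10 of 31 (corrected 6) and higher in 2, at percentile 3.15, short of the limit, with PRDX1 3.18-fold (2.94 to 3.44), TXN 2.86-fold (2.63 to 3.11; corrected 1.61-fold, no longer called) and SOD1 2.76-fold lower (2.52 to 3.03). MT1G, which has near-identical relatives, was 3.85-fold lower (2.52 to 6.05). Hypoxia and HIF targets, at percentile 30.1, had 2 of 20 higher and 6 lower: VEGFA was 4.49-fold higher (4.23 to 4.78; corrected 2.97-fold) and EPAS1 3.08-fold (2.60 to 3.66), while BNIP3 and LDHA were lower, as given above.

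Inflammatory genes did not move as a single group, although the cytokine receptor, NF-kB and immediate early lists were apart on the higher side. Of 27 cytokine and chemokine genes, 5 were higher (corrected 7) and 4 lower (corrected 3), at percentile 79.5 (corrected 95.6). CSF1, the macrophage growth factor, went from 15 to 271 reads, 13.4-fold higher (8.01 to 24.3), LTA from 2 to 34 reads, 12.6-fold (3.24 to 109), and TNF from 166 to 691, 3.10-fold (2.61 to 3.69). IL8 was 2.86-fold lower (1.53 to 5.54) at 34 and 16 reads, no longer called with the trend taken out, and SPP1 3.63-fold lower (2.73 to 4.88). IL1B had 10 and 11 reads, too few to show a difference. CCL2 had a fold of 2.07 (1.41 to 3.10), short of the limit, and was called higher with the trend taken out, at 3.35-fold. Cytokine and chemokine receptors were apart on the higher side, with 7 of 30 higher and 1 lower: TNFRSF1B was 2.69-fold higher (2.45 to 2.97), TNFRSF10B 2.49-fold (2.21 to 2.80) and TNFRSF12A 13.4-fold (3.45 to 115), whereas CXCR4 was 2.87-fold lower (2.65 to 3.11). CCR2, the receptor of CCL2, had 642 and 817 reads, a ratio of 1.06 in favour of normal glucose (0.951 to 1.17) whose direction turned with scaling to the total of gene counts. NF-kB components and targets, at percentile 99.3, had 3 of 27 higher (corrected 1) and 2 lower (corrected 1), with IRF1 2.40-fold higher (2.13 to 2.71), BCL3 2.74-fold higher (1.95 to 3.91), and SOD2 2.16-fold (1.81 to 2.58) and PLAU 1.99-fold lower (1.77 to 2.23); BCL3 and SOD2 were no longer called with the trend taken out. Immediate early and AP-1 genes, at percentile 99.7, had 7 of 29 higher (corrected 4) and 0 lower (corrected 1), among them FOSL2 (2.37-fold, 2.20 to 2.56), ATF3 (2.42-fold, 1.91 to 3.11) and IER2 (2.55-fold, 2.22 to 2.95). Toll-like receptor and inflammasome genes had 6 of 25 higher (corrected 2) and 0 lower, at percentile 57.0 (corrected 97.54, just past the limit), with IRAK2 3.20-fold (2.02 to 5.28) and NLRP1 2.62-fold higher (1.83 to 3.83; no longer called with the trend taken out). For NADPH oxidase, 3 of 9 genes were higher (corrected 0), CYBA by 1.89-fold (1.71 to 2.09), NCF4 by 1.65-fold (1.55 to 1.77) and NOXA1 by 2.36-fold (1.61 to 3.53); CYBB had a ratio of 1.05 in favour of normal glucose (0.827 to 1.34), which turned likewise. The median of that list was -0.08 and its mean 0.15 on the log2 scale, and it was at percentile 39.9.

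Monocyte and macrophage markers went both ways, with 9 of 40 higher (corrected 7 of 39) and 8 lower (corrected 7), at percentile 76.7 (corrected 7.2). Their median log2 fold was 0.04, and -0.24 with the trend taken out. CD14, the lipopolysaccharide co-receptor, went from 22 to 217 reads, 7.34-fold higher (4.72 to 12), and SIGLEC1 was higher as given above; S100A8 was 6.16-fold (3.26 to 12.6) and MNDA 3.31-fold lower (3.0 to 3.67). MHC class II genes were lower in 6 of 9 and higher in 0, at percentile 0.04: besides HLA-DRA (chromosome 6, 32515625 to 32520802), HLA-DPA1 was 6.18-fold (3.08 to 13.7), HLA-DQB1 2.51-fold (1.93 to 3.28) and HLA-DRB1 1.92-fold lower (1.73 to 2.14). HLA-DRA, HLA-DPA1 and HLA-DRB1 are listed at several places, so their reads are uncertain. Without genes at several or shared places, too few members were left to place this list. Granule and progenitor genes were lower in 5 of 15 and higher in 0, at percentile 16.8, including the protease gene PRTN3 (3.57-fold, 3.42 to 3.73), MS4A3 (3.99-fold, 3.68 to 4.32), RNASE2 (2.47-fold, 2.40 to 2.55) and the stem cell factor receptor gene KIT (4.56-fold, 3.52 to 5.95). Integrin and adhesion genes were higher in 8 of 28 (corrected 6) and lower in 1, at percentile 86.8 (corrected 26.1), led by ITGB5 (4.47-fold, 3.54 to 5.70) and ITGB7 (4.01-fold, 3.37 to 4.80). Metalloproteinase, matrix and coagulation genes were higher in 5 of 22 and lower in 3, at percentile 95.9 (corrected 98.5, apart), with MMP2 5.50-fold (4.06 to 7.60) and MMP14 3.18-fold higher (2.90 to 3.48) and F13A1 3.93-fold lower (3.30 to 4.71). Histone and DNA modifying enzymes were higher in 10 of 60 (corrected 2) and lower in 4, at percentile 96.6 (corrected 22.4). KDM6B, a demethylase of histone H3, was 3.60-fold higher (2.95 to 4.44; corrected 2.16-fold), and SETD7, a methyltransferase of histone H3, 1.84-fold (1.66 to 2.04). CREBBP, MLL2 and HDAC5 were each higher as well, but not with the trend taken out.

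Markers of other cell types were at low levels. Reads of 65 T and NK cell, B cell, erythroid and platelet, and epithelial and fibroblast markers came to 626 in normal and 910 in high glucose, a fold of 1.08 (0.976 to 1.20). By list, the T and NK cell markers had 90 and 97 reads, the B cell markers 417 and 455, the erythroid and platelet markers 21 and 86 (3.05-fold, 1.87 to 5.17) and the epithelial and fibroblast markers 98 and 272 (2.06-fold, 1.63 to 2.63). Fewer than 5 members of each list were measured. Among them PAX5 (7.81-fold, 4.08 to 16.8), GP9 (5.06-fold, 1.97 to 16.6), GP1BA (3.81-fold, 1.76 to 9.42) and CLDN7 (3.62-fold, 2.53 to 5.30) were higher, BANK1 was 1.77-fold lower (1.51 to 2.08; no longer called with the trend taken out), and the T cell gene CD8A and the NK cell gene NKG7 were neither. Of the non-polyadenylated and nuclear RNAs that follow library preparation, 0 of 3 measured replication-dependent histone genes were called. With the trend taken out HIST2H4A, which shares its reads with the copy HIST2H4B, was called higher. Reads of 35 such histone genes together went from 74 to 145 (1.46-fold, 1.09 to 1.96), and those of 18 small and scaffold RNAs, most of them MALAT1, from 5786 to 19070 (2.45-fold, 2.38 to 2.53). Of 4 small and scaffold RNAs, 3 were higher: RMRP, at 1 and 24 reads, MALAT1 (2.73-fold, 2.63 to 2.82) and NEAT1 (1.79-fold, 1.69 to 1.90).

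Transcript usage within genes differed for 604 transcripts of 343 genes, 10.2% of the 3350 genes that could be compared, by at least 25 percentage points of the gene's reads. The largest difference was in ZNF493, where the transcript NM_175910 held 11.9% of the reads in normal glucose (exact interval 6.39 to 19.2) and 77.7% in high glucose (70.6 to 84.1). The other named genes were TACC1, with 1 transcript at 17.7% and 78.1%, PABPC4 at 29.4% and 85.1%, FNDC3A at 27.0% and 82.3%, DYRK1A at 29.4% and 84.1%, and PBX3 at 4.11% and 58.5%. None of these 6 genes was called higher or lower as a whole. Reads that fit several transcripts were divided by the authors' software, and the intervals leave out the error of that division. In 264 of the 343 genes, the transcript that gained most in high glucose was longer than the one that lost most. Whether this follows the length trend between the libraries was not tested.

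By chromosome, the genes of 10 of 23 chromosomes were apart from random sets. Those of chromosomes 16, 17, 19 and 22 were higher, with medians between 0.16 and 0.24 on the log2 scale, and those of chromosomes 1, 2, 4, 12, 13 and X were lower, with medians between -0.24 and -0.06. With the GC and length trend taken out, chromosomes 13 and X remained apart on the lower side, chromosome 15 was apart on the higher side, and the others were not apart.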

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

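The correction for GC content and length, the scaling by library totals implied by RPKM and the removal of genes at several or shared places were chosen after the data were seen. No named gene that was called and no list apart turned its direction in an alternative run on it; CCR2, CYBB and IL1B, which were not called, changed sign in some, as did the medians of 5 lists that were not apart with the trend taken out. Of 35 lists, 12 were apart in every alternative run on them, 12 in none, and 11 changed their call in at least 1. These were 11 alternatives, or 10 for MHC class II, which had too few genes at a single place. Counts of genes higher and lower were 876 and 836 with the wider interval and 577 and 391 with a fold limit of 2; with the GC and length trend taken out, 898 were higher. The other counts of genes stayed within 1.5 times the value in the report. Of the 165 genes that the naming rule takes, the fold left its counting interval for 88 with the GC and length trend taken out, 64 with RPKM and a pseudocount of 1, 27 with the total of gene counts, 15 with the most abundant transcript and 13 with the totals implied by RPKM, and for 0 in the other alternatives run on genes. Percentiles that crossed a limit, by list, were as follows. With no read minimum, glycolysis was at 2.47 and NADPH oxidase at 98.84. With a minimum of 100 reads, cytokines were at 98.5 and antioxidant targets at 1.73. With the most abundant transcript, glycolysis was at 2.44, p53 targets at 99.81 and Toll-like receptor genes at 98.12. Against unmatched random lists, glycolysis was at 0.8 and antioxidant targets at 1.29. With the GC and length trend taken out, glycolysis was at 0.04, p53 targets at 99.71, Toll-like receptor genes at 97.54 and metalloproteinases at 98.46, all apart; the respiratory chain at 4.22, osmotic stress at 95.02 and insulin and mTOR at 93.19 were no longer apart, and 3 chromosomes were apart. Without genes at several or shared places, MHC class I was at 96.22. Isoform differences were found in 114 genes at 40 points and in 226 with 500 reads per gene and library. The stricter limits and minimums call fewer genes by construction; for the other settings the cause was not tested. Pseudocounts of 0.1 and 5 were not run, because reads were used. No paired analysis was possible because each glucose concentration had 1 library. At this depth a gene with 20 reads needs a large fold to be called.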

Other observations

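The families, gene runs and transcript lengths below, and the tests on GC content, length and other cell types, were chosen only after the data were seen; what each test on GC content, length or other cells would show was written down before its result, except for the reads of the abundant genes of other cells. Grouped by the shared start of their symbols, 101 families had at least 12 measured genes. Of these families, 6 were apart on the higher side and 14 on the lower side, where random sets of genes would give 5.05. That number likewise takes the genes of a family as moving independently. With the GC and length trend taken out, 15 were apart, and 7 of these had been apart on the same side before, all of them lower: RPL, RPS, the mitochondrial ribosomal family MRPS (corrected median log2 fold -0.26), the nuclear pore family NUP (-0.51), the glycosylation family ALG (-0.38), the centrosomal family CEP (-0.35) and TTC (-0.25). The families apart only with the trend taken out were HIST (corrected median 1.06, before 0.78) and PARP (0.39, before 0.24) on the higher side and ALDH, COL, CYB, KIF, NUDT and WDR on the lower side. The median of COL turned from 0.12 before to -0.53, and before the correction 3 of its 16 genes were higher and 0 lower. Some of the 14 HIST genes share their reads with a copy, so they are not separate measurements. In the semaphorin family SEMA, 6 of 15 genes were higher and 0 lower, with a median of 0.81 and, with the trend taken out, 0.44, which was no longer apart. In 264 of the 343 genes with a difference in transcript usage, the transcript that gained most in high glucose was longer than the one that lost most, and in 79 it was shorter.

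A run of 15 neighbouring genes on chromosome 1, from 40193371 to 41009860 (hg18, MFSD2A to NFYC), had the highest median level of 19834 such runs in both libraries, with 143 RPKM in normal and 136 RPKM in high glucose. In normal glucose, the median run had 2.28 RPKM and the 99th percentile of runs was 19.1 RPKM. In this run CAP1 had 85346 and 94078 reads and PPT1 70788 and 59948 reads, and COL9A2, a collagen gene of cartilage, had 8682 and 18201 reads. Away from this run, the highest was also on chromosome 1, from 42400949 to 43197434, at 48.5 RPKM in normal glucose.

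Interferon-stimulated genes were higher with a median of 4.24-fold. Taking out the GC and length trend left their median log2 fold at 2.08, above all random lists. The trend had an SD of only 0.32 on the log2 scale. A list this far out could hardly have come back among the random lists, so its place there decides little. What the values show is that a trend of this size is too small to account for the whole rise. Summed markers of T, B, erythroid, platelet, epithelial and fibroblast cells had a fold of 1.08 (far bound 1.20), but BANK1 made up 354 of their 626 reads in normal glucose, and the erythroid and platelet markers alone rose 3.05-fold (1.87 to 5.17) and the epithelial and fibroblast markers 2.06-fold (1.63 to 2.63). Cells of another type would also bring their abundant transcripts. In the high-glucose library there was 1 read for T or NK cells (CD3D, CD3E, CD3G, CD2) and 47 for B cells (CD79A, CD79B, MS4A1). There were 0 for red cells or platelets (globins, PPBP, PF4) and 14 for epithelial cells or fibroblasts (KRT8, KRT18, KRT19, COL1A1, COL1A2, COL3A1). Interferon-stimulated genes gained 73881 reads, which argues against each of these cell types as the source of those reads. The counts do not address a stimulus that a few such cells could give to the THP-1 cells. Interferon genes had 1 and 4 reads, too few to show or exclude a rise (2.98-fold, 0.294 to 147). Glucose, and a difference between the cultures such as an unnoticed interferon stimulus, may each underlie the pattern, and with 1 culture per concentration the design leaves both open.

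Genes of ribosomal proteins and of the respiratory chain were both lower, and their short transcripts make a technical trend a candidate explanation. For the ribosomal proteins, the median log2 fold went from -0.85 to -0.50 with the GC and length trend taken out and still lay below all random lists, so the trend does not account for the whole difference. For the respiratory chain it went from -0.69 (random lists -0.31 to 0.15) to -0.25, at percentile 4.22, because most of its fold was part of the trend; bias of GC content and length is therefore consistent with that pattern. The trend itself may hold a real change in short transcripts, which no test here separates from library preparation. RNAs that follow preparation went both ways. Histone RNAs and the small and scaffold RNAs were higher, 1.46-fold and 2.45-fold as sums, as was the HIST family with the trend taken out. Of the 5786 and 19070 reads of small and scaffold RNAs, MALAT1 held 4130 and 15139 and NEAT1 1608 and 3867. That sum therefore says little about the other small RNAs. The small nucleolar RNA families SNORA and SNORD were apart on the lower side, with median log2 folds of -0.54 and -0.51. Some small nucleolar RNA genes overlap a ribosomal protein gene on the same strand, as SNORD21 and SNORA66 do with RPL5. These families may therefore not be independent of the ribosomal protein genes. With the trend taken out, SNORA was no longer apart (0.03), and SNORD had no corrected value. An effect of glucose stays open for both the ribosomal protein and the respiratory chain genes.

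The sets of chromosomes that were higher or lower followed GC content: across chromosomes, Spearman's rho of the mean GC content of the genes and their median log2 fold was 0.81. With the trend taken out, 2 of the 10 chromosomes were still apart on the same side, which lies between the limits set beforehand for GC content and transcript length bias as the cause or not. That bias may therefore account for most of the pattern, but with it taken out chromosomes 13 and X were still lower and chromosome 15 was apart on the higher side. A difference in chromosome number between the cultures was not tested.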
